A study of Homo sapiens with 8 samples.

How the data were processed

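Small RNA was sequenced from HCT116, a human colorectal cancer cell line with wild-type p53, grown as adherent cultures at passages 16 to 19. In 4 libraries the cells had been co-cultured for 6 hours with enterotoxigenic Bacteroides fragilis (ETBF), a gut bacterium that secretes a metalloprotease toxin, at a multiplicity of infection of 500 bacteria per cell. The other 4 libraries came from control cells, which received the bacterial medium without ETBF per the labels' protocols and are titled untreated. Samples were grouped by their titles. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these samples, which may be technical in part.

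The deposited files hold raw read counts per mature miRNA name, 1 file per library with the same 2575 names in each. The authors' reads were processed with Trimmomatic, FastQC and featureCounts against GRCh37.p5, per the submitters' processing notes. Their versions, the aligner, the miRNA annotation release and the strand setting are not given in the sources used here. A total of 1013 names had counts above 0 in at least 4 libraries, and for 43 of these every count was a multiple of the same whole number of 2 or more. Of the 43, 36 belong to miRNAs with 2 or more hairpin genes, such as hsa-miR-129-5p, so reads of these appear to have been counted once per genomic copy. The pattern did not hold for every multi-copy miRNA: hsa-miR-24-3p, with hairpins miR-24-1 and miR-24-2, had 33747 counts in ETBF replicate 1. Where it holds, the factor is constant per miRNA. The factor then raises the level of such a miRNA and leaves the ratio of its counts between groups as it is. It also overstates the number of reads behind the value, so the SE and p of such a miRNA can be too small, which was not corrected. MiRNAs of near-identical sequence (the let-7 family, miR-17-5p with miR-106a-5p, miR-103a-3p with miR-107) can share reads, and their levels are uncertain for that reason. The name hsa-miR-149 carries no arm, so its value is given under that name and not for either arm.

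Library totals ran from 2591655 to 6522542 counts. A level of 3 counts, the limit that a count of 0 allows, corresponds to 0.46 to 1.16 CPM (counts relative to the library total) depending on the library. That limit covers counting error only, since reads without molecular identifiers are not independent molecules. Within a group no pair of libraries was identical or differed only by sampling noise: chi-square per degree of freedom lay between 18.4 and 111.9.

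Fold changes were computed in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 on the counts as deposited, with TMM normalisation, a 2-group design and the default expression filter at a minimum count of 10. This left 480 miRNAs, which held over 99.9% of the counts of each library. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 480, with a threshold of 0.05. CPM values are normalised with the TMM factors and given as mean ± SD. The standard error (SE) of a log2 fold change is approximate, being the fold change divided by the square root of its F statistic.

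Before the data were examined, 16 lists of miRNAs were fixed: miR-149, inflammation-responsive miRNAs, the miR-200 family, gut epithelial miRNAs, the let-7 family, the miR-17-92 cluster with its paralogs, p53 targets, the miR-183 cluster (miR-183, miR-96 and miR-182), colorectal oncomiRs, hypoxia and stress miRNAs, markers of blood, of stroma and muscle and of neurons and liver, the imprinted chromosome 14 cluster, the chromosome 19 cluster, and entries that overlap or resemble other RNA classes. Lists with at least 3 tested members, 14 of the 16, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, using a preset correlation between miRNAs of 0.01 and an estimated one, and with fry, which asks whether the members of a list move one way on balance without comparing them with other miRNAs. List p-values were adjusted over the 14 lists.

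The ratio of the 5p and 3p arms was tested for the 118 hairpins whose arms both passed the filter, with limma on log2 of the ratio of counts after adding 0.5 to each, adjusted over the 118. The minor arm is the one with the lower mean over the 8 libraries. Totals, detected miRNAs and shares of abundant miRNAs were compared by a two-sided exact permutation test over the 70 arrangements of the libraries, whose smallest p is 0.0286, adjusted over 4 measures.

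The miRNAs named were chosen by a rule fixed in advance. It takes miR-149, the 10 largest rises and 10 largest falls among miRNAs past the threshold with a mean of at least 10 CPM in a group and no overlap between the groups, and the 5 most abundant miRNAs. It adds up to 4 members past the threshold per list by abundance (or the 2 most abundant where none passed) and the 3 hairpins with the smallest p for the arm ratio. Any other miRNA named was chosen after its values were seen.

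The alternatives were RLE, upper-quartile or total-count scaling, no filter or at least 10 CPM in 4 libraries, limma-voom, DESeq2 1.42.0, the replicate number as a block, the most abundant miRNA or the other-RNA entries left out, each library left out in turn, a pseudocount of 5 for arm ratios, and detection at 5 counts or after thinning. Thinning of every library to 2591655 counts for the fold changes, and removal of each library's trend with GC content, were added after the data had been seen. GC content was taken from the side of the hairpin that holds each arm, or from the whole hairpin where the name carries no arm, as for hsa-miR-149. It came from GENCODE v29 transcripts and existed for 479 of the 480 miRNAs. Genes whose interval contains a hairpin were taken from RefSeq on GRCh38.p14. Because this build differs from that of the counts, only names and base composition were used and no coordinates are given.

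The fits were tested on simulated counts drawn from the means and library sizes of these libraries. Each simulated miRNA was given the spread typical of its abundance, so miRNAs that vary more than that were not covered. Among 478 simulated miRNAs tested, 33 of 50 changed by 1.5-fold and 39 of 43 changed by 2-fold were called in the right direction, and 2 of 385 unchanged ones were called. A simulated raised list was found with no other list called. Of the 118 hairpins in the arm simulation, 17 of the 20 changed ones were found, with 1 false call among the unchanged ones. The simulated miRNAs were drawn independently, so false list calls from correlated members were not covered. In the data the estimated correlation was 0.133 for the miR-17-92 list and 0.232 for the other-RNA entries.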

Results

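MiRNA counts were obtained from 8 libraries of whole-cell RNA from HCT116 cells, 4 after 6 hours with ETBF and 4 controls. The series concerns ETBF in intestinal inflammation and colorectal carcinogenesis, and the comparison asks which cellular miRNAs differ soon after contact with the bacterium. The ETBF libraries held 4706156, 4036551, 3879570 and 2591655 counts for replicates 1 to 4, and the control libraries held 5274167, 6040266, 5243400 and 6522542. The mean total was 3803480 ± 883828 with ETBF and 5770090 ± 622501 in controls (SD, n = 4 each; exact permutation p = 0.0286, the smallest this design allows, adjusted p = 0.0571). Counts above 0 were seen for 959 ± 52.1 miRNAs with ETBF and 1049.5 ± 26.1 in controls (exact permutation p = 0.0286, adjusted p = 0.0571), and this order turned after thinning to equal depth, with 893 against 883.5 (exact permutation p = 0.429). The most abundant miRNA was miR-21-5p, with 35.3% ± 1.93 of counts with ETBF and 34.5% ± 0.899 in controls (SD, n = 4 each, exact permutation p = 0.486). The 10 most abundant miRNAs together took 76.3% and 75.4% (exact permutation p = 0.171). Correlations of log2 CPM lay between 0.990 and 0.995 within groups and between 0.977 and 0.985 across groups.

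Cells exposed to ETBF had more miR-4521, more of the minor arms of miR-21, miR-222 and miR-16-1, and less miR-129-5p, miR-149 and miR-210-3p than control cells. Of the 480 miRNAs tested, 95 were higher and 70 lower with ETBF, and 315 did not pass (edgeR, adjusted over all 480). At an unadjusted p under 0.05 there were 209. Changes were mostly small: 27 of the miRNAs that rose and 6 of those that fell changed by 2-fold or more. The ETBF and control values did not overlap for 142 of the 165 called miRNAs. Among all tested miRNAs 162 were without overlap, where chance gives 2.86%. Of the 91 miRNAs with up to 40% GC in their side of the hairpin (the whole hairpin for names without an arm), 24 rose and 2 fell. Of the 96 above 60% GC, 14 rose and 22 fell. With upper-quartile scaling the split was 71 higher and 89 lower (44.4% higher, against 57.6% with TMM).

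MiR-149 fell. It was named in advance as a list of its own because the study is known for following it in exosomes. That choice came from the study's related samples, so it is not an independent prediction. Its entry hsa-miR-149, which names no arm and whose hairpin lies within the proteoglycan gene GPC1, was at 2103 ± 751 CPM with ETBF and 5702 ± 494 CPM in controls (SD, n = 4 each), 2.71-fold lower, with a log2 fold change of -1.44 (SE 0.20, adjusted p = 4.43e-05). All 4 ETBF libraries lay below all 4 controls. ETBF replicate 4 was the lowest at 1011 CPM, against 2208 to 2608 CPM in the other 3. The list of the miR-149 arms had this 1 tested entry and no list test.

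The largest rise was that of miR-7641, an entry whose sequence resembles ribosomal RNA, from 12.6 ± 6.59 to 93.0 ± 10.2 CPM (log2 fold change 2.86, SE 0.23, adjusted p = 1.09e-07). The rise with the smallest p was that of miR-4521, whose hairpin lies outside annotated genes: it went from 141 ± 9.49 to 695 ± 65.0 CPM, 4.95-fold (log2 fold change 2.31, SE 0.09, adjusted p = 1.16e-11). Minor arms, the less abundant products of their hairpins, made up 5 of the other 8. The minor arm miR-16-1-3p, from a hairpin in the tumour suppressor locus DLEU2, rose from 2.82 ± 0.409 to 12.7 ± 2.03 CPM (log2 fold change 2.17, SE 0.21). MiR-222-5p, whose partner arm represses the cell cycle inhibitor CDKN1B, rose from 23.8 ± 4.85 to 77.5 ± 18.4 CPM (1.70, SE 0.17). MiR-128-1-5p (1.67, SE 0.18), miR-92a-1-5p from the miR-17-92 cluster (1.56, SE 0.16) and miR-21-3p (1.40, SE 0.08, from 318 ± 23.3 to 839 ± 48.0 CPM) also rose. The set was completed by miR-451a, an erythroid miRNA matured by AGO2 instead of Dicer (1.94, SE 0.35), miR-3687 from the ribosomal RNA unit (1.72, SE 0.34) and miR-7974 (1.33, SE 0.10).

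The largest fall was that of miR-129-5p, a brain-enriched miRNA often silenced by methylation in tumours, from 58.6 ± 4.79 to 4.58 ± 1.85 CPM, 12.3-fold lower (log2 fold change -3.62, SE 0.18, adjusted p = 2.67e-10). Its counts were 24, 18, 26 and 6 with ETBF and 304, 366, 284 and 372 in controls, all multiples of 2, so each read appears to have been counted once per hairpin copy, and its SE and p can be too small. MiR-210-3p, the classic hypoxia-induced miRNA, fell from 679 ± 36.6 to 252 ± 37.1 CPM, 2.70-fold (-1.43, SE 0.10, adjusted p = 1.47e-08). MiR-935 (-1.40, SE 0.15) and miR-642a-3p (-1.29, SE 0.19) fell by similar factors. Smaller falls were those of miR-574-3p (-0.95, SE 0.09), miR-409-3p (-0.86, SE 0.19), miR-3909 (-0.85, SE 0.15), miR-1292-5p from an intron of the snoRNP gene NOP56 (-0.78, SE 0.17) and miR-615-3p from the HOXC locus (-0.78, SE 0.09). After thinning to equal depth miR-1292-5p was at -0.61 with an adjusted p of 0.0547.

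**Figure D1:**
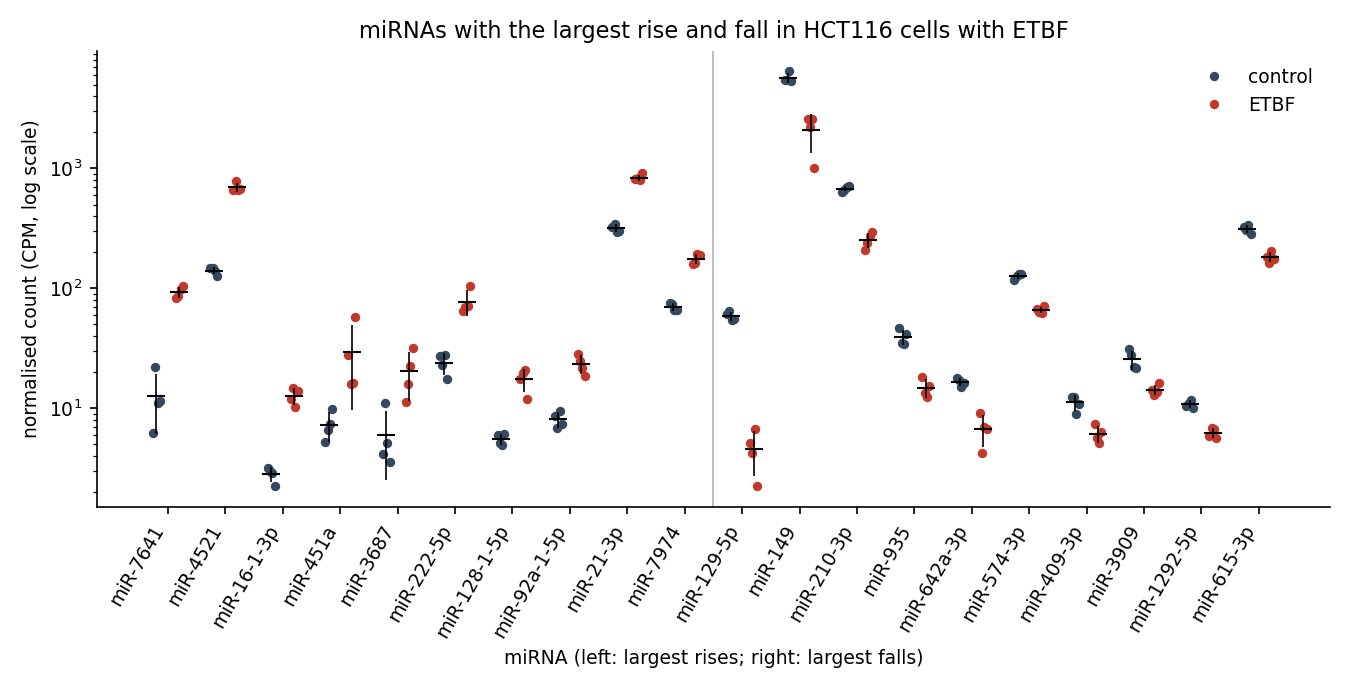
Normalised counts (CPM, logarithmic axis) of the miRNAs with the largest rises (left) and falls (right); each point is 1 library, blue for control and red for ETBF, with horizontal bars at the mean and vertical bars for the SD (n = 4 each). The groups are fully separated for each miRNA shown, by the naming rule, with miR-129-5p at 4.58 CPM with ETBF and 58.6 CPM in controls.

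The most abundant miRNAs stayed close to their control levels. MiR-21-5p, the main oncogenic miRNA of colorectal tumours, was at 346676 ± 26993 CPM with ETBF (log2 fold change -0.02, SE 0.07), and its sign turned with total-count scaling. MiR-7-5p (0.12, SE 0.08), miR-100-5p (-0.06, SE 0.13) and let-7f-5p (-0.11, SE 0.06) did not pass either. After removal of the GC trend let-7f-5p was at -0.27 and passed (adjusted p = 0.00275). Let-7a-5p was 1.16-fold lower (-0.21, SE 0.06, adjusted p = 0.0170), a call lost with total-count scaling (adjusted p = 0.0852) and without ETBF replicate 3 or 4 or control replicate 3 (adjusted p = 0.0747, 0.0573 and 0.0684).

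The miR-17-92 cluster and its paralogs, MYC-driven clusters that promote proliferation, were the list with the most members higher: 11 of 18 rose, 0 fell and 7 did not pass, and 12 were higher when adjusted over the list alone. MiR-20a-5p rose from 3520 ± 318 to 5456 ± 223 CPM (log2 fold change 0.63, SE 0.07), miR-17-5p by 0.60 (SE 0.10), miR-93-5p by 0.47 (SE 0.10) and miR-106b-3p by 0.24 (SE 0.07). The abundant miR-92a-3p (-0.00, SE 0.08) and miR-25-3p (-0.13, SE 0.07) did not pass. The mean log2 fold change was 0.41, and the list stood above the other miRNAs with camera (adjusted p = 0.0154 with the preset correlation, adjusted p = 0.342 with an estimated correlation), while fry gave an adjusted p of 0.00151. With upper-quartile scaling 7 members rose and 1, miR-25-3p, fell. The miR-106b-3p call was lost with that scaling, without a filter and without ETBF replicate 3 (adjusted p = 0.142, 0.17 and 0.0519).

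Among miRNAs induced by NF-kB, AP-1 or Toll-like receptor signalling, more fell than rose: 2 of 14 tested members were higher, 5 lower and 7 did not pass, with a mean log2 fold change of -0.14 (camera adjusted p = 0.240; fry adjusted p = 0.0131, downward). The fry call was lost in 4 of 19 alternatives and pointed up in 2 of them, with total-count scaling (adjusted p = 0.969) and with the stricter filter (adjusted p = 0.662). Without a filter the mean was -0.47 and the list passed with camera (adjusted p = 0.0281 with the preset correlation, adjusted p = 0.195 with an estimated correlation). The minor arm miR-21-3p rose (1.40, SE 0.08), while its far more abundant major arm miR-21-5p, also in the list, did not pass (-0.02, SE 0.07). MiR-29b-3p rose too (0.31, SE 0.08), a call lost after removal of the GC trend (0.15, adjusted p = 0.132). MiR-222-3p fell from 9480 ± 549 to 6134 ± 318 CPM (-0.63, SE 0.07) and miR-146b-5p, a feedback regulator of NF-kB signalling, fell from 536 ± 66.8 to 381 ± 30.1 CPM (-0.49, SE 0.09). MiR-132-3p (-0.68, SE 0.11), miR-132-5p (-0.44, SE 0.13) and miR-212-5p (-0.94, SE 0.23), from 1 locus and named after their values were seen, also fell. MiR-146a-5p was at -0.42 (SE 0.24, adjusted p = 0.204). MiR-155-5p had 0 counts over the ETBF libraries and 2 over the controls and was not tested.

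Hypoxia and stress miRNAs fell more often than they rose, with 5 lower, 1 higher and 5 not passed of 11 (mean log2 fold change -0.16, camera adjusted p = 0.184, fry adjusted p = 0.00124). Besides miR-210-3p, the abundant miR-24-3p (-0.31, SE 0.07), miR-27a-3p (-0.57, SE 0.07) and miR-22-3p (-0.50, SE 0.10) fell, and the member that rose was miR-27a-5p (0.79, SE 0.09). Colorectal oncomiRs, which are often raised in colorectal tumours, went both ways: 6 of 16 were higher, 3 lower and 7 not passed (mean 0.14, camera adjusted p = 0.779, fry adjusted p = 0.0206, upward). The fry call was lost in 12 of 19 alternatives, among them RLE (adjusted p = 0.254), total-count (adjusted p = 0.0746) and upper-quartile scaling, where it pointed down (adjusted p = 0.755). MiR-103a-3p (0.37, SE 0.07), miR-31-5p (0.34, SE 0.10) and miR-17-5p rose, while miR-222-3p fell. The miR-31-5p call was lost with upper-quartile scaling and without ETBF replicate 1 or 2 (adjusted p = 0.0621, 0.0516 and 0.0798). In the miR-183 cluster of miR-183, miR-96 and miR-182, also raised in colorectal cancer, 0 of 4 members passed with edgeR, limma-voom or DESeq2 and 0 had an unadjusted p under 0.05, with miR-182-5p at -0.08 (SE 0.06) and miR-183-5p at 0.06 (SE 0.06). The list had a camera adjusted p of 0.779 and a fry adjusted p of 0.358, and fry passed downward with upper-quartile scaling, without a filter and without ETBF replicate 3 (adjusted p = 0.0186, 0.0110 and 0.0189).

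The 2 epithelial lists passed neither camera nor fry, and the direction of fry turned in 5 and 7 of 19 alternatives. In the miR-200 family, which holds cells in the epithelial state, 3 of 9 rose, 3 fell and 3 did not pass. The mean log2 fold change was 0.09 and the median -0.03. Camera pointed down (adjusted p = 0.904) and fry up (adjusted p = 0.716). The 3 that rose, miR-141-5p (0.51, SE 0.09), miR-200a-5p and miR-200c-5p (0.69, SE 0.25), were all minor arms. The 3 that fell were the major arms miR-200c-3p and miR-200a-3p and the entry miR-429. Of the 4 most abundant arms, miR-200c-3p (-0.32, SE 0.07), miR-200a-3p (-0.19, SE 0.06) and miR-429 (-0.23, SE 0.07) fell and miR-200b-3p, the second most abundant, did not pass (-0.03, SE 0.08, adjusted p = 0.795), and miR-200a-5p (0.30, SE 0.10) rose. These calls, except that of miR-200c-3p, were lost in several alternatives, with adjusted p up to 0.166 for miR-200a-3p, 0.130 for miR-200a-5p and 0.0826 for miR-429. All 3 were lost without ETBF replicate 3 or 4, miR-200a-3p and miR-200a-5p also without control replicate 3 or 4, and miR-200a-3p also without ETBF replicate 1 or control replicate 2. Of 11 gut epithelial miRNAs 3 rose, 2 fell and 6 did not pass (mean 0.06, camera adjusted p = 0.904, fry adjusted p = 0.716). MiR-31-3p (0.69, SE 0.11) and the keratinocyte miRNA miR-203a (0.42, SE 0.09) rose, and miR-375, an endocrine and epithelial miRNA, fell from 368 ± 16.4 to 249 ± 5.02 CPM (-0.56, SE 0.07). In the let-7 family, tumour suppressors that repress RAS genes, 2 of 9 fell, 0 rose and 7 did not pass (mean -0.12, camera adjusted p = 0.164, fry adjusted p = 0.00523, downward), with let-7d-5p at -0.35 (SE 0.07). The fry call was lost with total-count scaling (adjusted p = 0.322). After removal of the GC trend 4 fell and the list mean was -0.19 (camera adjusted p = 0.0489 with the preset correlation, adjusted p = 0.268 with an estimated correlation). Of 6 tested p53 targets 2 rose and 4 did not pass, and 3 were higher when adjusted over the list alone (mean 0.20, camera adjusted p = 0.458, fry adjusted p = 0.0131, upward): miR-34a-5p rose from 188 ± 13.4 to 248 ± 20.9 CPM (0.40, SE 0.09) and miR-107 by 0.39 (SE 0.07). The fry call of the p53 targets was lost in 5 of 19 alternatives, with an adjusted p of 0.116 with upper-quartile scaling.

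Of 8 tested entries that overlap or resemble ribosomal RNA, snoRNA or repeats, fixed as a sign of RNA quality, 5 were higher, 0 lower and 3 did not pass, with a mean log2 fold change of 1.18 (camera adjusted p = 0.0320 with the preset correlation, adjusted p = 0.342 with an estimated correlation; fry adjusted p = 0.00323). They included miR-7641, miR-3687 and miR-1303 (0.84, SE 0.14). MiR-6087 (1.51, SE 0.49, adjusted p = 0.0247) was at 445 CPM in ETBF replicate 4 and at 79.1 to 155 CPM in the other ETBF libraries, and without that library its log2 fold change was 0.73 (adjusted p = 0.161). Its call was also lost without control replicate 1 or 4 (adjusted p = 0.0517 and 0.0721) and with DESeq2 (adjusted p = 0.105). The list's call was lost without ETBF replicate 3 or 4 or control replicate 1 or 4 (adjusted p = 0.0634, 0.105, 0.171 and 0.0980) and with the stricter filter (adjusted p = 0.155). Without a filter, with 25 members tested, the mean was 0.50 (adjusted p = 0.0193 with the preset correlation, adjusted p = 0.195 with an estimated correlation).

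Lists of markers of other cell types did not pass with camera in the main fit, while fry was downward for neuronal and liver markers and for the chromosome 14 cluster. Of 7 tested blood and endothelial markers 1 rose, 1 fell and 5 did not pass; the mean log2 fold change was 0.11, the median -0.09, and camera (adjusted p = 0.648) and fry (adjusted p = 0.133) pointed down. Fry passed with upper-quartile scaling, without control replicate 3 and after thinning (adjusted p = 0.00233, 0.00993 and 0.0281). MiR-451a rose, with 58.0 CPM in ETBF replicate 4 and 16.0 to 27.5 CPM in the other ETBF libraries, whereas the erythroid miR-486-5p was at 35.4 ± 4.77 with ETBF and 37.8 ± 3.34 CPM in controls and the leukocyte miR-142-3p at 12.8 ± 2.19 and 12.5 ± 2.23 CPM. The endothelial miR-126-3p fell (-0.43, SE 0.08). Of 6 stromal and muscle markers 1 rose, miR-145-3p (0.67, SE 0.12), and 5 did not pass (mean -0.01, camera downward with an adjusted p of 0.904, fry upward with an adjusted p of 0.716). MiR-145-3p is a minor arm, and the major arm miR-145-5p was at 0.03 (SE 0.10). Of 6 neuronal and liver markers 2 fell, miR-129-5p (-3.62) and miR-128-3p (-0.47, SE 0.08), and 4 did not pass (camera adjusted p = 0.150, fry adjusted p = 0.00323). The mean was -0.83, drawn down by miR-129-5p, and the median -0.38. In the imprinted chromosome 14 cluster 1 of 11 fell, miR-409-3p, and 10 did not pass (mean -0.29, camera adjusted p = 0.164, fry adjusted p = 0.00985, a call lost without ETBF replicate 2 with an adjusted p of 0.0561). With the preset correlation both lists passed without a filter (means -0.54 and -0.45, adjusted p = 0.0495 each) and after removal of the GC trend (-0.89 and -0.41, adjusted p = 0.0453 each). With an estimated correlation they did not (adjusted p = 0.368 and 0.263 without a filter, 0.268 each after GC removal). The placental chromosome 19 cluster had 0 members with enough counts to test. Adjusted over the list alone, the counts were the same as over all 480 miRNAs in every tested list except the miR-17-92 and p53 lists given above.

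**Figure D2:**
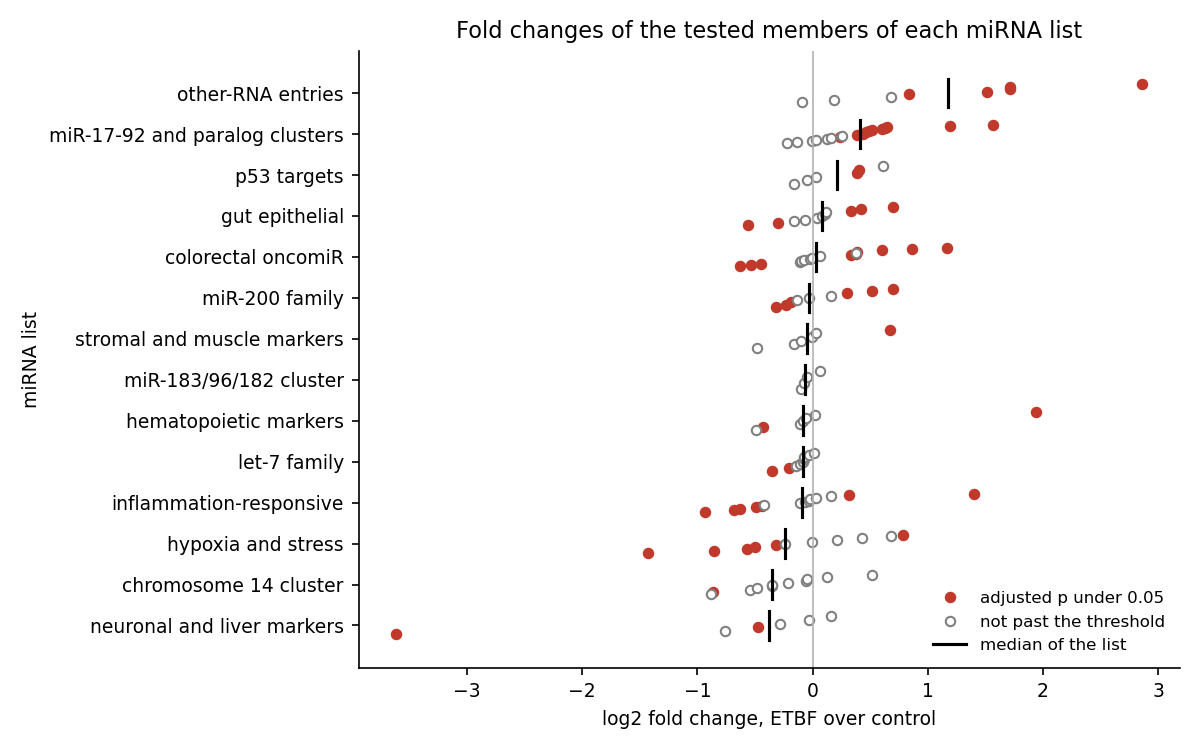
Log2 fold change (ETBF over control, horizontal axis) of each tested member of the 14 tested miRNA lists (vertical axis), ordered by median; filled red points passed an adjusted p of 0.05, open points did not, and black bars mark the median. The other-RNA entries (mean 1.18) and the miR-17-92 list (mean 0.41) lie mostly to the right of 0. Both also have members to the left, such as miR-664a-3p (-0.09) and miR-93-3p (-0.22).

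The ratio between the arms of a hairpin was compared because it is measured within a library and needs no scaling. For 38 of 118 hairpins the ratio changed (limma, adjusted over the 118): in 31 the minor arm rose relative to the major arm and in 7 it fell. The miR-21 hairpin, which lies within VMP1, had the smallest p: its minor arm miR-21-3p went from 0.0902% to 0.241% of the hairpin's reads, a log2 change of the ratio of 1.42 (SE 0.12, adjusted p = 5.12e-05). The minor arm miR-222-5p went from 0.251% to 1.25% of the miR-222 reads (2.32, SE 0.20, adjusted p = 5.12e-05) and miR-27a-5p from 5.68% to 13.4% of the miR-27a reads (1.36, SE 0.15, adjusted p = 0.000126). The same direction was seen for miR-25, miR-135b and miR-30d, and the opposite for miR-33a, miR-340 and miR-642a, examples chosen after their values were seen. Taken singly, 33 minor arms rose and 11 fell, and 18 major arms rose and 30 fell. Over all 118 hairpins the minor arm was higher relative to the major in 75, with a median change of 0.20. Without ETBF replicate 4, the shallowest library, 25 hairpins changed, 23 of them among the 38, and in 20 the minor arm rose.

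**Figure D3:**
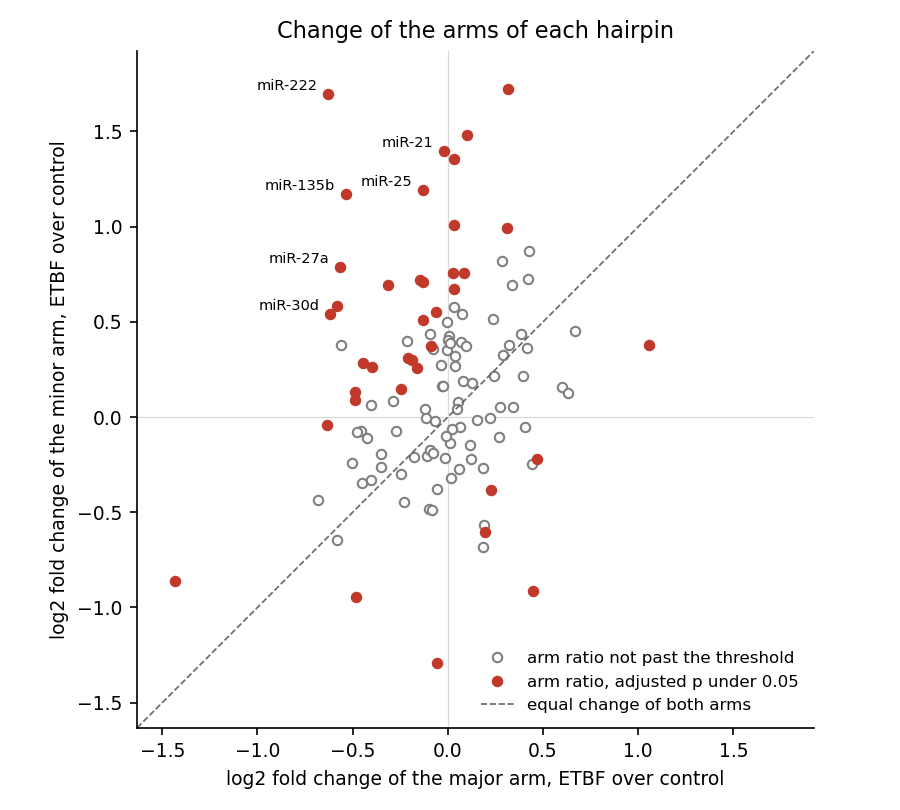
Log2 fold change (ETBF over control) of the minor arm (vertical axis) against that of the major arm (horizontal axis) for 118 hairpins; filled red points are the 38 whose arm ratio passed an adjusted p of 0.05, and the dashed line marks equal change. Most red points, 31 of 38, lie above the line, with the 6 of smallest p labelled.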

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

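The test of miR-149 without ETBF replicate 4 was chosen after its result was seen, and the thinned and GC-corrected fits, the GC correlation and the tests of a shift towards minor arms were chosen after the data had been seen, while the test of each hairpin's arm ratio was planned.

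Within a group of 4 libraries, 7 of 118 groups checked held a library far from the other 3, where chance gives about 5.9. For miR-149, control replicate 3 was at 6438 CPM and the other controls at 5378 to 5498. For miR-4521, ETBF replicate 2 was at 791.4 CPM and the others at 656.7 to 673.7. For miR-222-5p, ETBF replicate 4 was at 104.8 CPM and the others at 64.68 to 70.89. For miR-93-5p, control replicate 1 was at 1709 CPM and the others at 2347 to 2435. For miR-34a-5p, ETBF replicate 4 was at 216.7 CPM and the others at 255.5 to 262.2. For miR-103a-3p, control replicate 2 was at 12540 CPM and the others at 10660 to 10800. For miR-1303, control replicate 4 was at 12.38 CPM and the others at 9.862 to 9.943.

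The number of miRNAs called, 165, was reached by 1 of the 35 splits of the 8 libraries into 4 and 4, the real one. The highest of the other splits gave 0. Each other split mixes ETBF and control libraries, which widens the spread within its groups, and 1 of 35 is the smallest share possible. The splits therefore argue against chance without excluding it. Depth differed between the groups, but after thinning to equal totals 144 of the 165 were still called in the same direction, which argues against depth as the main cause. Fold changes also fell with GC content, defined as above (Spearman rho -0.244 across 479 miRNAs, permutation p = 1e-05, the smallest possible). These miRNAs are not independent replicates. Removing each library's GC trend still left 136 of the 165 called in the same direction. The exposure to ETBF, the biological difference in the design, stays open. So does a difference in preparation or RNA quality between the groups, which was not tested, since the labels name no batches. The other-RNA entries, fixed as a sign of RNA quality, differed with the groups: 5 of 8 were higher with ETBF and 0 lower (mean log2 fold change 1.18, camera adjusted p = 0.0320 with the preset correlation, adjusted p = 0.342 with an estimated correlation).

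The number of hairpins with a changed arm ratio in either direction, 38, was reached by 1 of the 35 splits, the real one, with 0 in the highest other split. The shift towards minor arms, as the median change over all 118 hairpins, was 0.2011. Of the 35 splits 1, the real one, gave an absolute median as large, with 0.1298 in the highest other split. As 1 of 35 is the smallest share possible, this argues against chance without excluding it. After thinning, the median was 0.2347 over the 105 hairpins whose arms both still passed the filter. For those hairpins this argues against the lower depth of the ETBF libraries as its cause. In a regression on the GC difference of the arms, the intercept was 0.1942 (SE 0.0562). This is a fitted mean change at equal GC and not a median. It lay above 0 by more than 2 SE, but that SE treats the 118 hairpins as independent although all come from the same libraries. A change in hairpin output that both arms follow equally leaves their ratio as it is, so by itself it cannot give the 38 changed ratios or the shift. A change in output that the arms follow unequally could give them, and it was not tested. Whether the arms shared a change was asked by correlation. The Spearman rho across 118 hairpins, which are not independent replicates, was 0.127 (permutation p = 0.170), and Pearson r was 0.134 (permutation p = 0.148). These are too small and too uncertain to decide. The exposure to ETBF stays open and was not tested apart from preparation. Degraded or bacterial RNA read as minor arms was not tested either, and the higher other-RNA entries given above leave it open.

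The fall of miR-149 was -1.185 (SE 0.197) after removal of the GC trend and -1.212 (SE 0.0884) without ETBF replicate 4, where it was lowest. Neither the fitted trend with GC content, here that of the whole hairpin, nor that library therefore accounts for all of it. Mature sequences were not used, so a bias tied to the mature sequence was not tested. Which arm fell stays open, since the entry names none. A response of the cells to ETBF stays open too and was not tested apart from preparation.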

How the results depend on the processing

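Thinning for fold changes and removal of GC trends were chosen after seeing the data. Over the 20 alternatives, calls ranged from 71 to 106 higher and from 59 to 89 lower, and 136 to 163 of the 165 calls were kept. Of 1093 values for the 55 named miRNAs under these alternatives, 1050 kept direction and side of the threshold, 36 lost a call, 1 (let-7f-5p after GC removal) gained one and 6 turned sign, none of the last from a miRNA that had passed. The replicate numbers did not pair the samples (correlations of same-numbered deviations 0.0283, 0.0608, -0.0584 and 0.0344), and with the replicate block 92 miRNAs were higher, 67 lower and 28 hairpins changed. MiR-21-5p was at 0.0336 with total-count scaling, 0.00361 after thinning and -0.0807 to 0.00473 with 1 library left out, miR-100-5p at -0.192 to 0.0651 with 1 left out, miR-183-5p at -0.0212 with upper-quartile scaling and miR-7-5p at -0.00138 after GC removal. List means that turned sign had lain near 0. The stromal list was at 0.0457 with total counts, 0.211 without a filter, 0.101 with the stricter filter, 0.00299 without the most abundant miRNA, 0.00674 without other-RNA entries, 0.115 after thinning and -0.0333 to 0.0497 with 1 library left out. The gut epithelial list was at -0.0189 with upper-quartile scaling, -0.197 without a filter and -0.0239 to 0.0680 with 1 library left out, and the miR-183 cluster at 0.0140 with total counts. Without a filter, which adds members with few counts, the inflammation list (-0.469, adjusted p = 0.0281), the neuronal and liver list (-0.540, adjusted p = 0.0495) and the chromosome 14 list (-0.448, adjusted p = 0.0495) passed, and their adjusted p over alternatives ranged from 0.0281 to 0.749, from 0.0453 to 0.295 and from 0.0453 to 0.265. After GC removal the neuronal (-0.892), chromosome 14 (-0.406) and let-7 (-0.187) lists passed (adjusted p = 0.0453, 0.0453 and 0.0489). With an estimated correlation these lists did not pass (adjusted p = 0.195, 0.368 and 0.263 without a filter, 0.268 for each of the 3 after GC removal). The other-RNA list kept its direction at 0.4997 without a filter, 1.38 with the stricter filter, which leaves fewer members, and 0.790 to 1.22 with 1 library left out, without its call in 5 of 18 alternatives. The miR-17-92 list passed in each of 19 with the preset correlation of camera, to which all list calls here refer. With an estimated correlation it passed in 0 of 19 (adjusted p from 0.262 to 0.834). Fry lost or gained calls under alternatives for the inflammation, let-7, p53, miR-183, oncomiR, blood and chromosome 14 lists, and kept its call and direction in all alternatives for the miR-17-92, hypoxia, neuronal and other-RNA lists (highest adjusted p = 0.0180, 0.0214, 0.0140 and 0.0180). Changed hairpins ranged from 25 to 38 and those with a raised minor arm from 20 to 31 with 1 library left out, and 4 had a lowered minor arm after thinning. The difference in detected miRNAs was -45.25 at 5 counts or more and 9.5 after thinning to equal depth, so detection near the floor follows depth. Apart from fewer libraries, members or counts, the cause was not tested.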

Other observations

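The groups and miRNAs in this part were picked after their values were seen. Among abundant miRNAs not yet described, several fell by less than 2-fold. MiR-26a-5p, which represses the methyltransferase EZH2, went from 27438 ± 779 to 19513 ± 1124 CPM (log2 fold change -0.49, SE 0.06), miR-30d-5p from 16214 ± 1146 to 10550 ± 410 CPM (-0.62, SE 0.07) and miR-148a-3p from 21263 ± 2798 to 15514 ± 1507 CPM (-0.45, SE 0.09; SD, n = 4 each, edgeR adjusted p = 1.87e-05, 3.30e-06 and 0.00118). MiR-125b-1-3p, the minor arm of a miR-125b hairpin in MIR100HG, rose from 152 ± 13.5 to 370 ± 21.3 CPM (1.28, SE 0.08, adjusted p = 1.15e-08).

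Calls were also counted by the gene whose interval contains the hairpin, in groups with at least 4 tested miRNAs and without a test of the grouping. In FTX, a noncoding RNA gene of the X-inactivation centre, 4 of 5 miRNAs rose and 1 did not pass, with miR-374a-3p at 0.87 (SE 0.10) and miR-374b-5p at 0.42 (SE 0.10). In MIR17HG, the host of the miR-17-92 cluster, 5 of 9 rose and 4 did not pass. These 9 leave out the cluster products miR-92a-3p (-0.00, SE 0.08), which did not pass, and miR-19b-3p (0.49, SE 0.14), which rose. In MCM7, a replication licensing gene that hosts miR-25, miR-93 and miR-106b, 4 of 6 rose and 2 did not pass, miR-25-3p at -0.13 and miR-93-3p at -0.22. With upper-quartile scaling these counts were 4 higher in FTX, 3 higher in MIR17HG and 3 higher with 1 lower in MCM7, and after GC removal 3, 4 and 4 higher. In CLCN5, which hosts the miR-532 and miR-500a hairpins, 1 of 12 rose, 1 fell and 10 did not pass, with 3 lower under upper-quartile scaling. Each library's slope of log2 CPM on GC content was taken relative to the mean over libraries. It averaged -0.0462 ± 0.0235 per 10 points of GC with ETBF and 0.0462 ± 0.00641 in controls (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). The group means mirror each other by construction, so only their difference carries information, not the sign in either group.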
